A study of Drosophila melanogaster with 2 samples.

How the data were processed

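Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on mixed-sex Drosophila melanogaster embryos aged 0 to 16 hours. The flies carried a transgene for CG11723 with GFP fused at its C-terminus, and chromatin sonicated to 200 to 800 bp was precipitated with an antibody against GFP, per the labels. The labels number the 2 samples as biological replicates 1 and 3 of 1 group. No input, untagged or unrelated GFP sample was analysed here, so no comparison between groups was possible.

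The analysis started from region lists in narrowPeak format that the authors deposited, 4 for each of the dm6 and dm3 genome builds. Per the submitters' file notes, regions were called on each replicate's alignments and on the alignments of both replicates pooled, with a control, and were listed before thresholding. The same notes state that the final list was derived from both replicate lists and the pooled list by the irreproducible discovery rate (IDR), and it is called the IDR list below. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The deposited signal value of each region, a peak caller's measure of enrichment, has a scale that is not stated, and it was used only to rank and describe regions within a list. The deposited −log10 q value was capped within each list, and 3069 of the 3869 regions of the dm6 IDR list (79.3%) stood at the maximum of 3.79, so it could not order them. Read numbers are not part of the lists, and the sequencing depth of each sample is therefore unknown here.

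Coordinates are dm6, counted from 1. No dm6 region ended past its arm in the reference sequence (Release 6). Gene models came from Ensembl release 115 (BDGP6.54), without transposable element models, and held 18277 genes, 13968 of them protein-coding. Sequence came from the RefSeq assembly of the same release. The dm3 lists served only for checks that need no genome sequence, and no coordinates were converted.

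A region was called a promoter region when its summit lay within 500 bp of an annotated transcription start site (TSS), and distal otherwise. The lower-ranked regions were the 25168 regions of the pooled list that overlapped no IDR region. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Promoter shares and arms were compared with 2-sided Fisher exact tests, and promoter shares also with 1000 random placements on the same arm. Signal medians were compared with a 2-sided permutation test of 100000 resamples. Replicates were compared by the overlap, by at least 1 bp, of their 3869 regions of highest signal, against 1000 random draws from their full lists. They were also compared by Spearman's rho across IDR regions, with 1000 bootstrap draws. Regions and genes are not biological replicates, and p-values across them measure no spread between embryo collections.

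For 24 gene lists, the share of genes with an IDR summit within 500 bp of a TSS was compared with that of other genes by Fisher's exact test. The background was the genes with a region of the pooled list at a TSS, 5188 of them protein-coding. For lists of tRNA, snoRNA and snRNA genes it was the 6311 such genes of every biotype. Names missing from the annotation were resolved through RefSeq synonyms for 4 names, and 1 name was not found. The eggshell pattern also matched 2 proteins outside the eggshell, which were taken out after the matched names were read and before any test value was seen. For sequence, 15 motifs and all 7-mers were counted on both strands in the 101 bp around each summit. The comparison window had the same width and was centred 500 bp away in the direction of lower coordinates, and the test was the exact McNemar test. The Benjamini-Hochberg adjustment was applied over lists, motifs or 7-mers, with a threshold of 0.05.

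The lists, motifs, tests and most alternatives were fixed before the data were examined. Genes named in the text are CG11723, the gene with the nearest TSS for each of the 20 IDR regions of highest signal, up to 3 members with the highest signal for each gene list, and every Hox gene. Other names were chosen after their values were seen, as stated beside them. The alternatives changed the TSS window (200 and 1000 bp), the position used for a region, the background genes, the comparison window, the overlap, the build and the number of regions. Each replicate was also left out in turn, by taking the 3869 regions of highest signal of the other replicate against the rest of its own list. Chosen after seeing the data were the composition-matched comparisons, the use of 1 region per block of overlapping regions, the feature classes other than promoters, the promoter share and GC content by rank, the position relative to the TSS, and the tests of single arms. In the matched comparisons, summit windows were paired with windows of the same promoter class and a GC content within 2 percentage points. The paired windows were first summits of lower-ranked regions, found for 3814 of the 3869 IDR summits, and the others were left out of that comparison. After 0 of 15 motifs passed in that comparison, a second was added with windows outside every pooled region, taken from 600000 random genome positions and not matched on coding exons. Such windows were found for all 3869 IDR summits. Fisher's exact test was used in both.

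Functions were tested on simulated data. With 20 7-mers planted in 3% of 4000 random genome windows, all 20 were called in both the flank comparison and the comparison of separate window sets; planted in 1%, 7 and 3 were called. Counting unplanted 7-mers too, the calls came to 61 and 54 at 3% and to 10 and 3 at 1%, so at 3% more 7-mers were called than were planted. Without planting, 0 of 8192 7-mers were called in either. These windows lay at random positions, so the runs do not measure calls that arise from a GC difference between summit and flank. A list of 30 genes with 90% of its members called was detected in 200 of 200 simulations, and a list of 10 genes in 153 of 200. A simulated promoter share expected at 56.7% was measured as 56.5% over 4000 regions. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.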

Results

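Genome-wide binding of CG11723, an uncharacterized Drosophila protein, was profiled by ChIP-seq through a GFP tag in whole embryos of both sexes. There was 1 group with 2 biological replicates, and the question was where in the genome the tagged protein was recovered. The IDR list on dm6 held 3869 regions on the 6 major arms, with a median width of 440 bp (110 to 1308 bp) and 1.28 Mb covered. These were exactly the regions ranked 1 to 3869 by signal in the pooled list of 30000. Their signal ran from 88.8 to 1646 with a median of 144. Some regions overlapped each other, and merging left 3613 blocks. The dm3 list held 3547 regions.

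The regions of highest pooled signal also ranked high in each replicate, which is partly built in because both contribute to the pooled signal. The region of highest signal, intronic and nearest to the TSS of CG11050, ranked 1 in replicate 1 and 4 in replicate 3, and those at Ugalt (a UDP-galactose transporter) and CG14100 ranked 3 and 4 in replicate 1 and 2 and 1 in replicate 3. Ranked separately, 63.4% of the 1000 strongest regions of replicate 1 overlapped one of the 1000 strongest of replicate 3. Of the 3869 regions of highest signal in replicate 1, 2329 (60.2%, 95% interval 58.6 to 61.7) overlapped one of the 3869 of replicate 3, against 7.57% on average and at most 8.84% in random draws from the full lists. Of the IDR regions, 2319 (59.9%) were among the top regions of both replicates, 775 of replicate 1 alone, 685 (17.7%) of replicate 3 alone and 90 (2.33%) of neither. Spearman's rho of the replicates' signal was 0.483 (bootstrap 95% interval 0.455 to 0.512) across the 3613 IDR regions present in both full lists. Regions are not independent replicates. With a 50% reciprocal overlap, the shared part of the top regions was 46.8%.

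IDR regions lay at promoters far more often than weaker regions did. Of the 3869, 1951 (50.4%, 48.8 to 52.0) had a summit within 500 bp of a TSS, against 5230 of 25168 lower-ranked regions (20.8%), an odds ratio of 3.88 (Fisher's exact test, p = 8.08e-306). Random placement gave 13.5% on average and at most 15.6% (1-sided permutation p = 0.000999, the smallest that 1000 placements can give). The share fell along the pooled ranking, from 70.6% of ranks 1 to 500 to 40.7% of ranks 3870 to 6000 and 14.6% of ranks 20001 to 30000. Introns held 33.9% of IDR regions against 46.3% of lower-ranked ones, intergenic sequence 13.1% against 25.6%, and coding exons 0.388% against 3.77% (Fisher's exact test, each adjusted p at most 1.51e-40). These classes held only summits outside the promoter window, so their shares fall as the promoter share rises. Of 1918 distal IDR regions, 1310 were in introns and 505 in intergenic sequence. The counts of lower-ranked regions were 11656 and 6450. The lower intron share thus does not mean that distal IDR regions avoided introns.

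**Figure D1:**
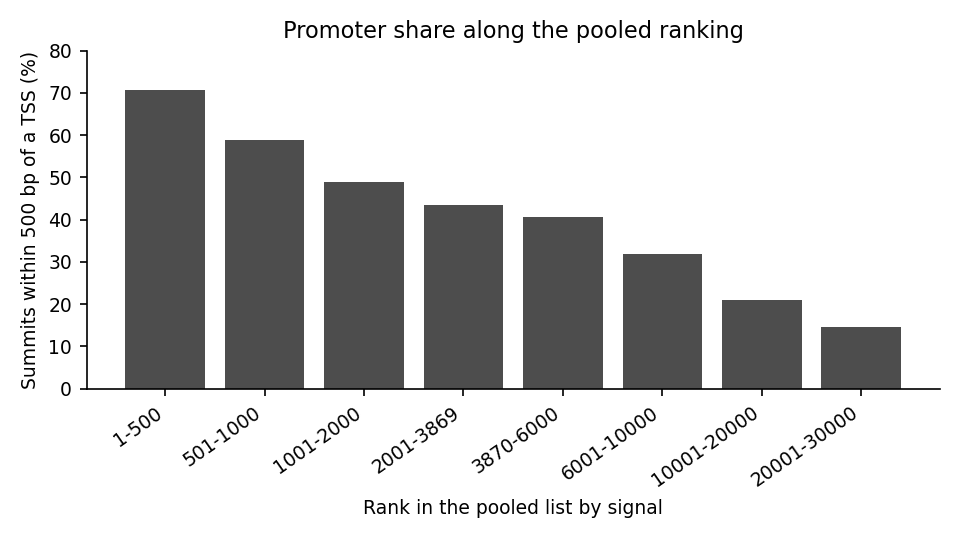
Share of regions with a summit within 500 bp of a TSS (vertical axis, percent) in successive ranges of rank by signal in the pooled list (horizontal axis). The share falls from 70.6% in ranks 1 to 500 to 14.6% in ranks 20001 to 30000.

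At protein-coding promoters the summits lay just upstream of the TSS. Of 1823 such IDR regions, 1481 (81.2%, 79.4 to 83.0) had an upstream summit, with a median position of -101 bp and quartiles of -204.5 and -26 bp. Of 4507 lower-ranked promoter regions, 56.2% were upstream, with a median of -24 bp (Fisher's exact test of the upstream shares, p = 3.41e-83). Promoter IDR regions also had higher signal, with a median of 159 (quartiles 112 and 253, n = 1951) against 134 (105 and 189, n = 1918) at distal ones. The difference of 25.4 had a permutation p of 1e-05, the smallest that the resamples can give. It was 15.3 in the signal of replicate 1 and 26.6 in that of replicate 3 at the same regions. In each replicate's own top regions it was 6.92 for replicate 1 and 16.8 for replicate 3.

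**Figure D2:**
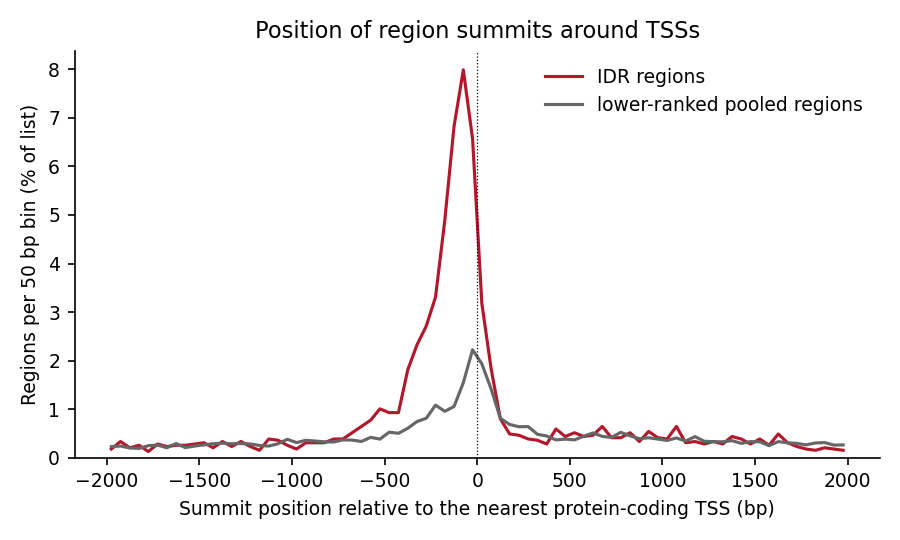
Position of summits relative to the nearest protein-coding TSS (horizontal axis, bp, negative upstream) as a percentage of each list per 50 bp bin (vertical axis). IDR regions (red) peak upstream of the TSS, with a median of -101 bp among promoter regions, and lower-ranked pooled regions (grey) have a lower peak with a median of -24 bp.

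The 20 regions of highest signal, 912 to 1646, lay mostly at promoters and in introns. Intronic and intergenic regions are named by the nearest TSS, which need not belong to the gene they lie in. The top region, 2L:6612389-6612980, lay in an intron and was nearest to the TSS of CG11050, at 1026 bp. The next was X:2703673-2704095, 28 bp from a TSS of Ugalt (signal 1568), followed by 3L:19590423-19590817, 98 bp from that of CG14100 (1558). Intronic regions were nearest to cbt, a zinc finger transcription factor (1492), CG32772 (1138), Trl, which encodes the GAGA factor (1099, 3L:14759297-14759750), HmgZ, an HMG-box protein (1075), CG9663 (991), and the kinase genes Lk6 (955) and Tlk (935). Promoter regions lay at px (1361), Gyf (1087), lncRNA:CR31840 (994), CG1888 (984), Tina-1 (966), Chro, which encodes a chromodomain protein (946, 3L:22878699-22879110), Pdrg1 (923) and lncRNA:CR44339 (914). The region nearest to CG13323 was intergenic, 11924 bp from the TSS (1053), and that of lncRNA:CR44619 lay in an exon (912). Every one of the 20 ranked among the top 43 regions of replicate 1 and the top 44 of replicate 3. Both replicates contribute to the pooled signal by which the 20 were chosen.

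Genes of the cytoplasmic ribosome carried IDR regions at their TSSs more often than other genes. Of 76 in the background, 68 (89.5%, 80.3 to 95.3) had one, against 39.6% of other coding genes, an odds ratio of 13.0 (Fisher's exact test, adjusted p = 6.79e-18). The regions of highest signal were at RpS27 (3R:25247338-25247695, 5 bp from the TSS, signal 671), RpL5 (658) and RpL7 (26 bp, 647). In single replicates the share was 89.7% in replicate 1 and 80.3% in replicate 3, with odds ratios of 16.1 and 5.49. The 8 without a region, named after their values were seen, were RpS2, RpS3, RpS9, RpS13, RpS24, RpS26, RpL35 and RpL40. The annotation held 92 such genes, and those without any pooled region at a TSS were not in the background.

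Architectural and promoter-binding proteins were also called more often, with 10 of 12 genes (83.3%, 51.6 to 97.9, Fisher's exact test, adjusted p = 0.0301), led by Chro, Cp190, an insulator protein (414), and Clamp, a zinc finger protein that binds GA repeats (376). So were translation factors, with 18 of 27 (66.7%, 46.0 to 83.5, exact test, adjusted p = 0.0438), led by eIF6 (727), eIF4EHP (680) and eEF5 (499). Both calls were weaker than that of the ribosomal proteins. That of architectural proteins was lost in replicate 1 alone (7 of 13, exact test, adjusted p = 0.589) and in the 1934 IDR regions of highest signal (6 of 12). That of translation factors was lost in replicate 1 alone (19 of 33, exact test, adjusted p = 0.0790) and in replicate 3 alone (16 of 31, adjusted p = 0.732).

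Transfer RNA genes carried IDR regions less often, 10 of 129 (7.75%, 3.78 to 13.8) against 37.6% of other genes (Fisher's exact test, adjusted p = 2.05e-13), the strongest being at tRNA:Tyr-GTA-1-8 (486), tRNA:Phe-GAA-1-2 (300) and tRNA:Trp-CCA-2-2 (228). The count was 23 of 144 in replicate 1 alone and 6 of 58 in replicate 3 alone. Chemosensory receptors and odorant-binding proteins had 1 gene of 19, Obp99b (5.26%, 0.133 to 26.0, exact test, adjusted p = 0.0115). That call was lost in replicate 1 alone (1 of 16, exact test, adjusted p = 0.0790) and kept in replicate 3 alone (1 of 25, adjusted p = 0.000113). It was lost too with a 200 bp TSS window (0 of 9) and in the 1934 IDR regions of highest signal (1 of 19). The region at Obp99b ranked 492 in replicate 1 and 8018 in replicate 3. The 1 gene in replicate 3 alone was therefore not called through that region.

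Lists of embryonic patterning genes held few genes in the background and did not pass the test. None of the 8 Hox genes (lab, pb, Dfd, Scr, Antp, Ubx, abd-A and Abd-B) had an IDR region at a TSS, and 5 of them were in the background. The gap genes had 0 of 7 (up to 41.0%), the pair-rule genes 1 of 4, at hry (signal 145), the segment polarity genes 2 of 9, at nkd (165) and ci (126), and the dorsoventral genes 2 of 11, at cact (252) and htl (175). Dorsoventral genes had 4 of 11 in replicate 1 alone and 5 of 12 with a 1000 bp TSS window, and Hox genes 1 of 5 in replicate 3 alone. The region at hry ranked 1111 in replicate 1 and 6256 in replicate 3, and that at ci ranked 1241 and 8535. Neural genes had 6 of 15, led by elav (624, a neuronal RNA-binding protein), Sox102F (241) and da (223), and muscle genes 3 of 13, tin (289), sls (279) and Tm1 (137). The region at da was absent from the list of replicate 3. Cuticle proteins had 0 of 9 (up to 33.6%, exact test, adjusted p = 0.0543). They were called lower in replicate 3 alone (0 of 32, exact test, adjusted p = 1.86e-07), with a 1000 bp window (2 of 20, adjusted p = 0.0234) and against all annotated genes (0 of 110, adjusted p = 1.88e-07).

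The other lists passed no test in the main setting. With all annotated genes as background, core histones (2 of 115, exact test, adjusted p = 1.23e-05) and snoRNA genes (16 of 269, adjusted p = 0.00105) were called lower. Most of these genes had no pooled region of any rank at a TSS, since only 4 of the 115 and 41 of the 269 had one. Mitochondrial ribosomal proteins had 15 of 32, with mRpL41 (901), mRpS23 (870) and mRpS10 (846) above every cytoplasmic ribosomal protein. Oxidative phosphorylation had 18 of 35, led by UQCR-11 (439), ND-ASHI (339) and ND-AGGG (257), and the proteasome 4 of 13, led by Prosalpha6 (445), Rpn5 (157) and Rpn3 (139). In replicate 1 alone oxidative phosphorylation had 13 of 40 and the proteasome 1 of 15, and in replicate 3 alone the proteasome had 5 of 10. Rpn5 and Rpn3 ranked 5877 and 5873 in replicate 1. Polycomb and Trithorax group genes had 7 of 13, led by ph-p (893), brm (574) and pho (570), and cell cycle genes 10 of 27, led by Dp (308), Cdk1 (288) and CycE (247). Heat shock proteins had 7 of 10, led by Hsp83 (626), Hsp27 (516) and Hsc70-5 (262), and core histones 2 of 4, His2Av (191) and His3.3B (97.1). Named MADF-BESS genes had 2 of 6, brwl (577) and hng3 (335), and 3 of 4 in replicate 3 alone. Small nucleolar RNA genes had 16 of 41, led by snoRNA:Me18S-G1358c (456) and by snoRNA:Psi28S-2949 and snoRNA:Or-aca5, which share a region (450), and small nuclear RNA genes 1 of 7, snRNA:7SKa (287), and 4 of 12 in replicate 1 alone. No chorion or yolk protein gene was in the background. A region between divergent genes counts for both of them.

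**Figure D3:**
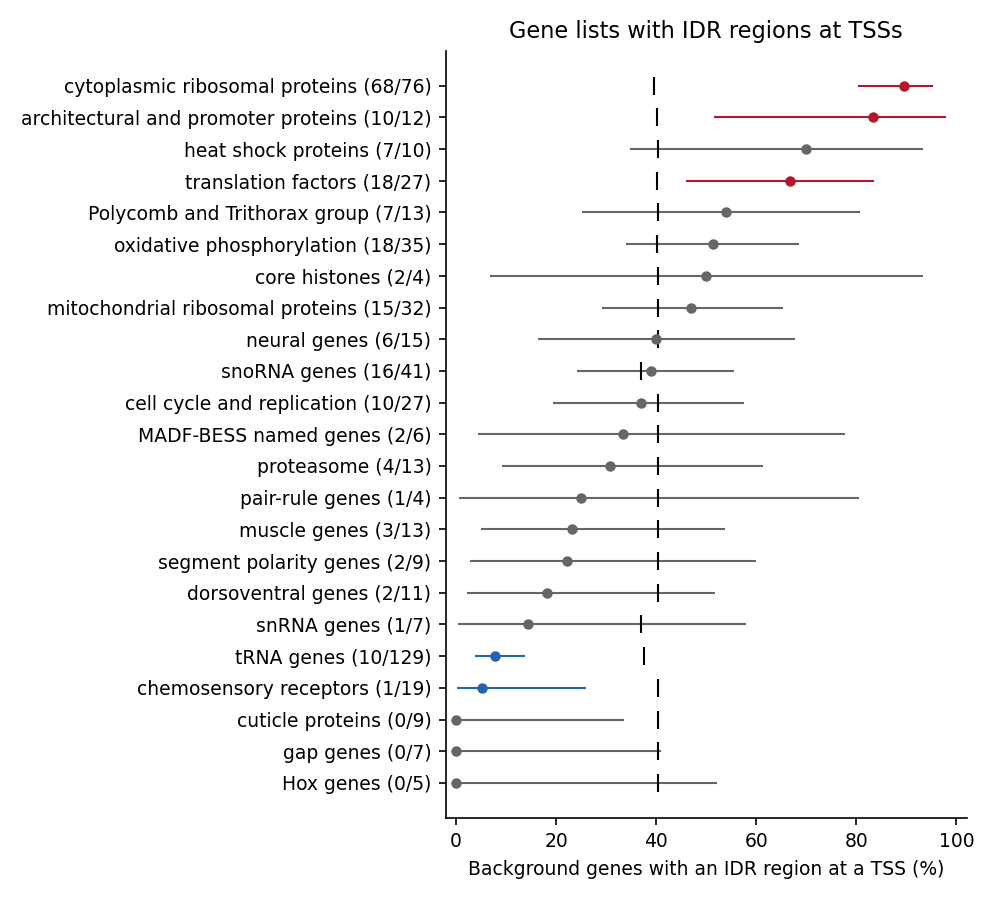
Share of background genes with an IDR region within 500 bp of a TSS (horizontal axis, percent) for each gene list, with the number of genes in brackets. Points are shares with exact 95% intervals, vertical ticks the share of other background genes, red lists are higher and blue lists lower at an adjusted p under 0.05. Cytoplasmic ribosomal proteins stand at 89.5% and tRNA genes at 7.75%.

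Sequence at the summits held more copies of the DRE (TATCGATA), the site of the promoter factor Dref, than the flanks did. It was found at 68 summits (1.76%) and in 19 flanks (0.491%, exact McNemar test, adjusted p = 4.63e-07), and its core TCGATA at 6.41% against 3.49% (adjusted p = 1.73e-08). Overlapping regions can count the same copy of a motif or 7-mer more than once. These counts were not repeated with 1 region per block. The CTCF core was at 38 summits against 9 flanks (0.982% and 0.233%, exact test, adjusted p = 6.23e-05) and Motif 1 at 25 against 10 (adjusted p = 0.0313). The TATA box (6.82% against 4.83%), GATA (21.4% against 16.9%) and runs of A and T (69.4% against 51.2%) were higher too, and the Adf1 repeat (5.94% against 10.3%) and the E-box CAGCTG (4.01% against 5.12%) lower, making 9 of 15 motifs called. Several differences were smaller in replicate 1 alone than in replicate 3 alone. DRE was at 1.11% of summits and 0.491% of flanks in replicate 1, and at 1.81% and 0.362% in replicate 3. Its core was at 5.30% and 4.06% in replicate 1 and at 6.88% and 3.70% in replicate 3. Runs of A and T were at 62.9% and 54.4%, and at 75.6% and 47.6%, and Adf1 at 7.83% and 9.82%, and at 4.11% and 10.6%. Motif 1 and the CTCF core went the other way, with larger differences in replicate 1 alone. Motif 1 was at 1.16% and 0.207% in replicate 1 and at 0.853% and 0.207% in replicate 3. The CTCF core was at 1.32% and 0.258%, and at 0.620% and 0.362%. GAGA, Zelda, Initiator, Pho, Su(Hw) core and the E-box CACGTG were not called in the main setting. GAGA differed in opposite directions in the replicates, higher in replicate 1 alone (3.83% against 2.61%, exact test, adjusted p = 0.00655) and lower in replicate 3 alone (1.27% against 2.89%, adjusted p = 1.14e-06). It was also lower in distal regions and with the comparison window on the other side. The E-box CACGTG was called lower in those 2 settings and in replicate 3 alone, and Initiator lower in replicate 3 alone. Su(Hw) core was called higher in replicate 3 alone and in the 1934 IDR regions of highest signal. The call of CTCF was lost in replicate 3 alone (24 summits and 14 flanks), those of the TATA box and the E-box CAGCTG in replicate 1 alone, and those of DRE, its core and Motif 1 in distal regions. Motif 1 was also not called in the 1934 IDR regions of highest signal. The E-box call was also lost in promoter regions, with wider windows and with the comparison window on the other side.

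Summits were also poorer in GC than their flanks, 36.2% against 42.2%, a difference of -6.07 percentage points (SE 0.239, n = 3869 regions), while lower-ranked regions differed by 0.987 (SE 0.0889). The difference was -2.85 (SE 0.246) in the top regions of replicate 1 and -9.21 (SE 0.227) in those of replicate 3. Motifs were also compared at matched GC content and promoter class, in 2 comparisons chosen after seeing the data. The matching itself removes differences that follow from base composition, such as that of runs of A and T. Against matched summits of lower-ranked regions, which were tried before any other control, 0 of 15 motifs passed Fisher's exact test. In these 3814 pairs DRE was at 67 summits against 42, its core at 246 against 220, the CTCF core at 37 against 17, GAGA at 73 against 65 and Motif 1 at 25 against 36. Matched genome windows outside all regions were added only after that result, and against them 5 motifs were higher and none lower. By Fisher's exact test these were DRE (68 against 19, adjusted p = 1.59e-06), its core (248 against 177, adjusted p = 0.00175), the CTCF core (38 against 5, adjusted p = 1.75e-06), GAGA (73 against 33, adjusted p = 0.000577) and Motif 1 (25 against 10, adjusted p = 0.0493).

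Of 8192 7-mers, 1253 differed between summits and flanks, 572 higher and 681 lower. Of the higher ones, 324 held at most 1 G or C, and of the lower ones 676 held at least 3. In single replicates 300 differed in replicate 1 and 2543 in replicate 3. Against the matched genome windows 85 were higher and 43 lower, and 44 were higher in both comparisons, 10 of these holding CAGTG or its complement. Of the 44, 23 were higher in the top regions of replicate 1, 38 in those of replicate 3 and 22 in both. This is partly built in, because only 2.33% of IDR regions were among the top regions of neither replicate. CTATCGA, which overlaps the DRE, was at 100 summits, 23 flanks (exact tests, adjusted p = 2.12e-10) and 25 matched genome windows (adjusted p = 1.53e-08). ACAGTGG was at 125 summits, 49 flanks (exact tests, adjusted p = 1.13e-06) and 28 genome windows (adjusted p = 3.47e-12), and CACAGTG at 116, 46 and 28. In promoter regions CTATCGA was at 83 summits and 16 flanks, and in distal ones at 17 and 7 (exact test, adjusted p = 0.361). GCAAACA was at 143 summits and 55 flanks of distal regions (exact test, adjusted p = 3.35e-07) and at 52 and 59 of promoter regions; these differences between classes were not tested. GCAAACA was not called in replicate 3 alone (128 and 127). Against matched lower-ranked summits 2 of 8192 7-mers passed, ACCGGAA (49 against 13) and AAGGAGA (13 against 48, Fisher's exact test, both adjusted p = 0.0290). CTATCGA (99 against 50) and ACAGTGG (125 against 79) did not.

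**Figure D4:**
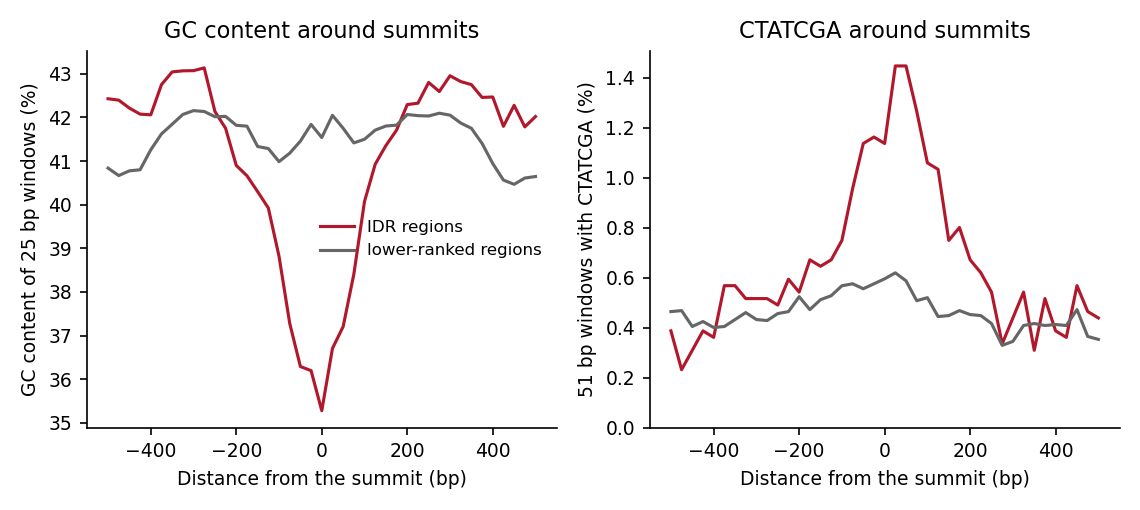
Mean GC content of 25 bp windows (left, percent) and share of 51 bp windows with CTATCGA (right, percent) by distance from the summit in bp, for IDR regions (red) and lower-ranked pooled regions (grey). GC content of IDR regions falls to 35.3% at the summit, against 41.5% for lower-ranked regions, and CTATCGA is at 1.14% and 0.596% there. The GC axis does not start at 0.

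The gene of the tagged protein itself, CG11723 (FBgn0031391, 2L:2145297-2147275, minus strand), had no IDR region within 5 kb. There were 9 within 50 kb and 3 within 20 kb, the latter against a mean of 1.64 for windows of the same width around all coding genes, of which 86.0% had as many or fewer. The strongest, 2L:2130449-2130812, ranked 101 (signal 604) and lay 198 bp from a TSS. A region of the pooled list at the 3' end of the gene, 2L:2145271-2145710, ranked 6083 and was not in the IDR list. In single replicates the 20 kb window held 5 regions in replicate 1 and 7 in replicate 3, and 96.3% and 99.3% of coding genes had as many or fewer. The transgene adds a copy of CG11723, which can raise reads over the genomic segment that it carries, and this was not tested.

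Chromosome 4, the small and largely heterochromatic autosome, had 118 IDR regions, 87.5 per Mb, against 26.6 to 31.1 per Mb on the other arms. It was as dense in the whole pooled list, with 616 per Mb, and it held 3.05% of IDR and 2.72% of lower-ranked regions (odds ratio 1.13, Fisher's exact test, p = 0.246). Of the other arms, 3L (odds ratio 0.864, Fisher's exact test, p = 0.000451) and 2R (0.891, p = 0.00922) held a smaller share of IDR than of lower-ranked regions, and 3R (1.14, p = 0.00242) a larger one, without adjustment for the number of arms. The 2R count was 720 in the IDR list, 812 in the top regions of replicate 1 and 697 in those of replicate 3. In the same order the counts were 820, 803 and 801 on 3L, and 852, 824 and 895 on 3R. The shares of these arms were not compared with lower-ranked regions within each replicate. The top lists of the replicates held 140 regions on chromosome 4 in replicate 1 and 76 in replicate 3. The X did not pass the test against the large autosomal arms, relative to lower-ranked regions (odds ratio 1.09, Fisher's exact test, p = 0.0670). That ratio was 1.33 in replicate 3 alone (exact test, p = 1.59e-09) and 0.967 in replicate 1 alone (p = 0.499).

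**Figure D5:**
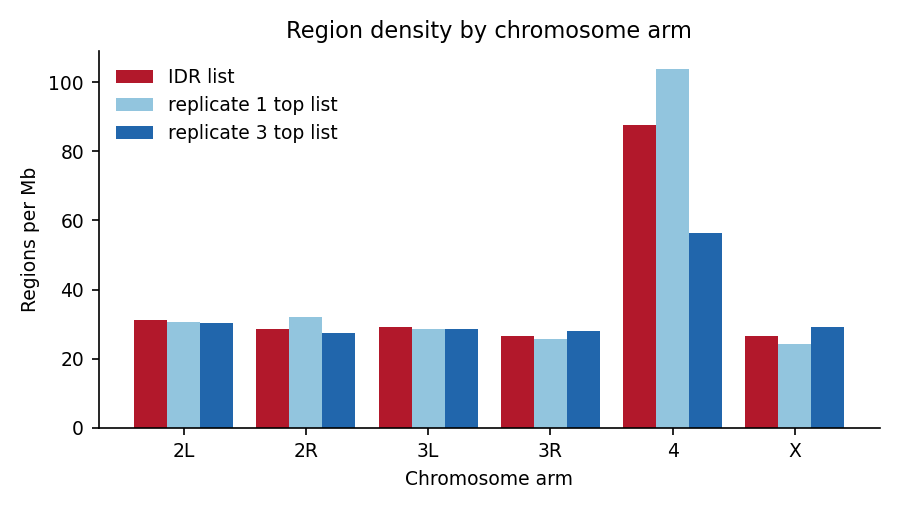
Regions per Mb (vertical axis) on each major chromosome arm (horizontal axis) in the IDR list (red) and in the 3869 regions of highest signal of replicate 1 (light blue) and replicate 3 (dark blue). Chromosome 4 stands at 87.5 in the IDR list, 104 in replicate 1 and 56.4 in replicate 3, and the IDR list gives 26.6 to 31.1 on the other arms.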

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

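The IDR list on the older dm3 build held 42 regions on sequences other than the 6 major arms. They entered Spearman's rho on the dm3 lists. The dm6 IDR list had no regions off the 6 major arms. Coordinates were not converted, so whether the same sites are among the dm6 regions on the arms is not known here. Of the 42, 16 were on 3LHet, 12 on 2RHet, 11 on 3RHet and 3 on 2LHet, the heterochromatin scaffolds of that build. Their median signal of 145 was close to the 150 of the whole dm3 list, and the strongest ranked 139. No dm3 sequence was used here, and no explanation was tested.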

How the results depend on the processing

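The comparisons with matched GC content and with 1 region per block were chosen after seeing the data. The promoter share exceeded that of lower-ranked regions in all 8 alternatives (34.6% to 61.0%, odds ratios 3.39 to 5.44), the signal difference stayed above 0 in all 5 (6.92 to 32.0), and rho stayed within 0.468 to 0.499 in all 3. The overlap of the replicates' top regions was 46.8% with a 50% reciprocal overlap, 63.1% for the top 1934 and 63.4% for the top 1000. The number of gene lists called was 3 for the 1934 IDR regions of highest signal, 8 with all coding genes as background, and 2 to 5 with a replicate left out. Ribosomal protein and tRNA genes kept their call in all 7 alternatives, with highest adjusted p of 8.63e-10 and 2.10e-05; the calls of translation factors, architectural proteins and chemosensory receptors were lost in 2, 2 and 3 of 7, with adjusted p up to 0.732, 0.589 and 0.238. Motif calls fell from 9 to 0 against matched lower-ranked summits, and to 5 against matched genome windows, a comparison added only after the 0 was seen. Part of this fall was built in, because GC matching removes differences that follow from base composition, such as that of A and T runs. Against lower-ranked summits the differences turned for Motif 1 (-0.288 percentage points), the TATA box (-0.184), the E-box CAGCTG (0.420), GATA (-0.105) and A and T runs (-1.94), and against genome windows for the E-box CAGCTG (0.827), Adf1 (0.982) and A and T runs (-0.414), none past the threshold. The number of 7-mers called was 486 in promoter and 227 in distal regions, 561 in the 1934 regions of highest signal, 128 and 2 in the matched comparisons, and 300 to 2543 with a replicate left out. The locus of CG11723 held 0 regions within 5 kb, 9 within 50 kb, and 5 to 7 with a replicate left out. The ratio of X to autosomes was 0.929 per Mb of length and 0.967 to 1.33 with a replicate left out. Where no construction is named, the cause was not tested. Read depth, a control and more replicates, which would limit these values, are not part of the lists used here. No paired analysis was possible because there is 1 group.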

Other observations

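Every test in this part was chosen only after the results above were seen, and for tRNA genes, the respiratory chain, replicate 1's GC content and the odds ratio of chromosome 4 the tested value itself had been seen. The design gives 1 group, so no biological explanation was tested.

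Some genes held many IDR regions along their bodies, and they were named after the counts were seen. CG1677 had 15 summits in 125 kb, kirre 13 in 394 kb, shn, a zinc finger transcription factor gene, 12 in 58.3 kb, and CHES-1-like, a forkhead gene, 11 in 27.0 kb. The GATA cofactor gene ush and sbb also had 11 each, and tara 10. The count at kirre came to 33.0 per Mb, near the 26.6 to 31.1 per Mb of the larger arms, against 407 per Mb at CHES-1-like. On chromosome 4, 52 of 80 coding genes had an IDR region at a TSS, the strongest after Gyf being anne (758), CaMKII (744) and CG32017 (651).

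IDR regions may favour genes with a divergent neighbour. Such a gene has a TSS that lies head to head with that of another coding gene within 1000 bp. Of 1823 promoter IDR regions, 44.3% had such a gene at the nearest TSS against 31.4% of 4507 lower-ranked ones (odds ratio 1.73, Fisher's exact test, p = 8.63e-22). The nearest TSS itself need not be the divergent one. Divergent pairs as the only cause of the upstream position are argued against by the remaining promoters. At promoters of genes with no divergent neighbour, 81.5% of 1016 IDR regions were upstream against 58.3% of 3091 lower-ranked ones (Fisher's exact test, p = 1.08e-43).

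Summits at ribosomal protein genes lay closer to the TSS than at other called genes. The median distance was 25 bp (n = 68 genes) against 149 bp (n = 2024), a difference of -124 bp (permutation p = 1e-05, the smallest the resamples can give). Each gene was measured to its strongest region within 500 bp of a TSS, so a region shared by neighbouring genes counted for each. The number of TSSs and divergent neighbours were not matched for this distance. The tables argue against the number of TSSs, divergent neighbours and GC content as explanations of the high share of ribosomal protein genes, 89.5%. Random gene sets matched on the number of TSSs and on divergent neighbours had a mean share of 42.4% and at most 60.5%, and sets matched on GC content around the TSS 42.3% and at most 59.2%. The tRNA genes stood at 7.75%. Their transcription was not measured, so they cannot decide on recovery at every heavily transcribed gene. Respiratory chain genes, at 51.4% (34.0 to 68.6), lay below the ribosomal protein interval of 80.3 to 95.3. Translation factors passed the test at 66.7% (46.0 to 83.5), and their interval reached that of the ribosomal proteins. Recovery at abundant housekeeping genes is thus left undecided, as it depends on the list taken. Recovery that rises with the level of RNA polymerase II transcription remains open, since no expression values or unrelated GFP sample were analysed here.

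The fall of GC content at IDR summits differed between the replicates. A bias of replicate 3's library alone is argued against by the -2.85 percentage points (SE 0.246) in replicate 1's own top regions. The signal ratio of replicate 3 to replicate 1 fell with GC content at the summit across 3613 regions (rho = -0.261, bootstrap interval -0.291 to -0.230). That relation largely restates the difference between the replicates, so a bias that differs between the libraries stays open. A bias shared by both libraries was not tested.

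The density of IDR regions on chromosome 4 may follow that of regions of any rank. The odds ratio against lower-ranked regions was 1.13 (0.923 to 1.37). That ratio covers the whole IDR list and may not hold for its strongest regions. The promoter regions at Gyf, anne, CaMKII, CG32017, CG31998, Arl4 and Crk, named after their values were seen, ranked 8, 38, 42, 77, 94, 97 and 100. The share of chromosome 4 among the strongest regions was not tested. AT-rich sequence is argued against as the whole cause, since chromosome 4 held 3.24 times (2.69 to 3.88) the number of IDR regions computed from 1 kb windows of the same GC content on the other arms. What makes regions of any rank dense there stays open.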
